A study of Mus musculus with 7 samples.

How the data were processed

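Total RNA from mouse primary keratinocytes had been extracted with Trizol, made into biotinylated complementary RNA and hybridised to Affymetrix arrays, 1 array per sample, per the labels. The deposited table held 1 intensity per probe set and array on a linear scale for 7 arrays. How the authors summarised probes, corrected background and normalised between arrays is not given in the sources used here. The deposited intensities were positive, with lowest values of 58.5 to 60.7 and highest values of 16436 to 17165 per array. The medians of the log2 values lay within 0.04 of each other, below the tolerance of 0.1 set before the data were examined, so the values were used as deposited. No genome build was needed and no coordinates are given.

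Samples were grouped by their labels into Trp63 siRNA (5 arrays) and control siRNA (2 arrays), all collected after 48 h. Of 22690 probe sets, 64 control probe sets were left out and 22626 were tested. The platform annotation gave 20380 of them 1 gene symbol, 691 several and 1555 none, and probe sets with several or no symbol were not used for genes. Of the named probe sets 20351 matched a current gene by Entrez ID. A gene was represented by its probe set with the highest mean over all arrays, which gave 12393 genes. Control probe sets for Gapdh and beta-actin and for bacterial spike transcripts were read only as measures of quality.

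Intensities became log2(intensity + 16), and fold changes are on that scale, which understates the change of dim genes. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjustment over all 22626 probe sets and a threshold of 0.05. Unless another setting is named beside it, the adjusted p of a gene is limma's from this fit. No filter on dim probe sets was applied and no detection calls were used. The 22 gene lists, with 478 of 530 entries measured, were fixed before the data were examined and tested with limma camera at a preset correlation of 0.01, adjusted over the 22 lists, and again with the estimated correlation. The lists were epidermal adhesion, basal keratinocyte, epidermal differentiation, activated keratinocyte, p53 pathway, mitosis, DNA replication, interferon response, Notch, TGF-beta and BMP, mesenchymal programme, Wnt, EGFR ligands and MAPK feedback, AP-1 and immediate early, cholesterol synthesis, endoplasmic reticulum and amino acid stress, hair follicle and appendage, literature p63 targets, and markers of fibroblasts, melanocytes, immune cells, and endothelium, blood, muscle and fat. Lists for simple epithelium, Merkel cells, mesothelium and sebaceous glands were written after the largest changes were known. Camera p-values of these lists were adjusted over them alone.

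The genes to name were set by a rule fixed before the data were examined. It took the p53 family, then the 12 largest rises and 12 largest falls among genes past the threshold, with a mean at or above the median of all probe sets and no overlap between groups. From each list it took up to 4 members past the threshold with the smallest p, or the 2 with the smallest p where none passed, and for the 4 marker lists of other cell types also the 2 brightest members. Lor, Lce1a1, Lce1b, Hrnr, Itgb4, Krt5, Krt16, Krt6a and Ccl20 were named after their values were seen, as were the genes of the other observations.

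RNA quality was compared with an exact two-sided permutation test over the 21 splits of the arrays into 5 and 2. The same procedure was tested on simulated data for 22626 probe sets in 5 and 2 arrays. It recovered 40 of 50 probe sets changed by 0.5 on the log2 scale, 93 of 100 changed by 1 and 50 of 50 changed by 2, made 13 false calls among 196 and none with no change. Of the 22 lists, only the 1 that had been shifted was called. Probe sets were simulated independently of each other, so this does not test the preset correlation where genes of a list move together. In the data the estimated correlation ran from -0.009 (p53 pathway) to 0.82 (melanocyte markers).

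Alternatives covered quantile normalisation, median centring, pseudocounts of 1 and 64, filters at the 25th and 50th percentile of mean level, eBayes without a trend or with robust estimation, array weights, other rules for the probe set of a gene, and leaving out each array. Leaving out a control leaves 1 control, which is then assumed to vary like the other group. Blocks and subsets for the spike and melanocyte splits were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.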

Results

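Messenger RNA levels were measured in mouse primary keratinocytes, the epithelial cells that build the epidermis, 48 h after transfection with small interfering RNA (siRNA). The series asks what silencing of Trp63 does to these cells. Trp63 encodes p63, a transcription factor of the p53 family that is needed for stratified epithelia. There were 5 arrays of cells given Trp63 siRNA (replicates 1, 2, 3, 4 and 7) and 2 arrays of cells given control siRNA (replicates 5 and 6), and no replicate number occurred in both groups. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Median probe set intensity lay between 208 and 215 on the 7 arrays. Their number limits the precision of every value below.

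Trp63 fell in all 5 silenced arrays. The brightest of its 3 probe sets read 503 ± 31.1 (SD, n = 5) with Trp63 siRNA against 1565 ± 167 (SD, n = 2) with control siRNA. This was a 3.05-fold decrease (log2 difference -1.61, SE 0.088, limma adjusted p = 1.0e-05), and 32.1% of the control intensity remained. The other 2 Trp63 probe sets were dimmer, at 235 and 209 in the controls, and differed by -0.49 and -0.54 on the log2 scale (limma adjusted p = 0.00228 and 0.000339). Trp73, the gene of the related factor p73, was lower at its brighter probe set, which was dim (151 against 185, log2 difference -0.27, SE 0.060, limma adjusted p = 0.0164), a call that ended when either control was left out (adjusted p = 0.113 without replicate 5 and 0.0936 without replicate 6). A second Trp73 probe set differed by -0.47 (limma adjusted p = 0.000622). Trp53 was not analysed here.

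**Figure D1:**
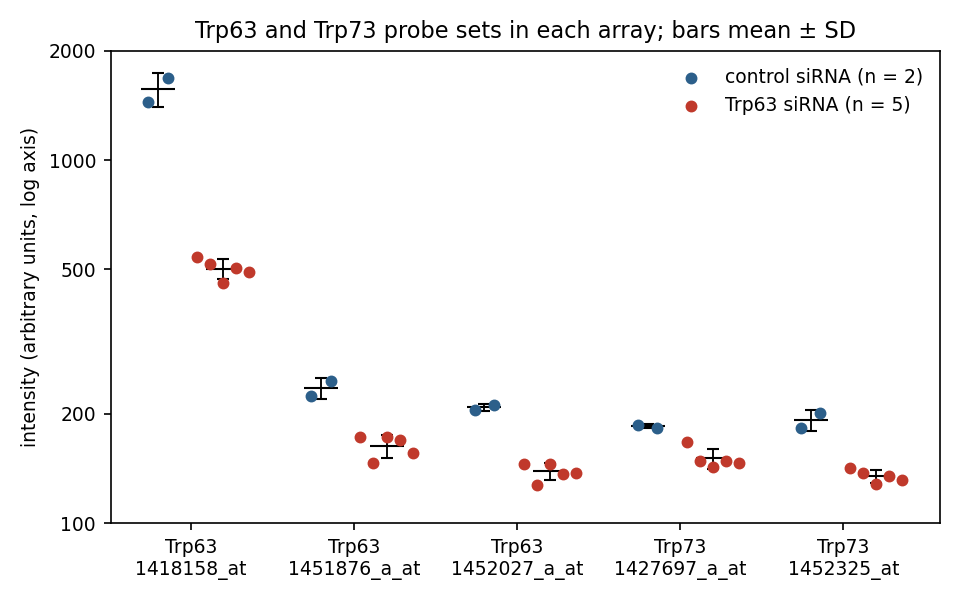
Intensity (log axis, arbitrary units) of the 3 Trp63 and 2 Trp73 probe sets in each array, with 1 point per array and black bars for mean ± SD. At the brightest Trp63 probe set the 5 Trp63 siRNA arrays lay between 457 and 541 and the 2 controls at 1447 and 1683.

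The 12 largest rises were led by Clu and Krt18. Clu, which encodes the secreted chaperone clusterin, rose 11.0-fold (log2 difference 3.45, SE 0.097, limma adjusted p = 2.6e-07). Krt18 and Krt8, the keratin pair of simple epithelia, rose 10.1-fold (3.33, SE 0.14) and 4.52-fold (2.18, SE 0.19). Krt18 read 1444 ± 196 (SD, n = 5) against 129 ± 26.7 (SD, n = 2). Control values of Krt18 (129), Krt8 (132), Krt79 (152) and Msln (113) lay below the array medians, near those of genes with no clear expression. The folds of these genes may therefore be understated and their ranks are uncertain. The tight junction gene Cldn3 rose 4.25-fold, and the surface or membrane protein genes Psca, Msln and Mal rose 5.43-fold, 4.82-fold and 4.81-fold. Bex1 (7.42-fold), Krt79 (6.86-fold), Spns2 (4.74-fold), which encodes a sphingosine-1-phosphate transporter, and the stress-induced Nupr1 (4.61-fold) completed the list with Dhcr7 (4.87-fold), an enzyme of the last step of cholesterol synthesis. Krt79 varied most, with 1245 ± 644 (SD, n = 5) in the silenced arrays.

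The 12 largest falls included 3 keratin genes and Trp63 itself. Tgfbi, a secreted matrix protein gene, was 4.81-fold lower (log2 difference -2.27, SE 0.21, limma adjusted p = 0.000169). Krt6b fell 3.51-fold, from 8335 ± 343 (SD, n = 2) to 2373 ± 252 (SD, n = 5). The differentiation genes Krt1, Krt10 and Ivl fell 3.47-fold, 2.88-fold and 2.81-fold. Dst, which encodes the hemidesmosome plaque protein of basal cells, fell 3.02-fold. Tnfrsf18 (3.19-fold), the inflammasome adaptor gene Pycard (3.14-fold), Serpinb6c (3.13-fold), the xanthine dehydrogenase gene Xdh (2.96-fold) and the mitochondrial creatine kinase gene Ckmt1 (2.81-fold) were the others beside Trp63. By the rule that chose them, every gene named here as a largest rise or fall had its 5 silenced values on 1 side of both controls. Their limma adjusted p was 0.00761 or lower.

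**Figure D2:**
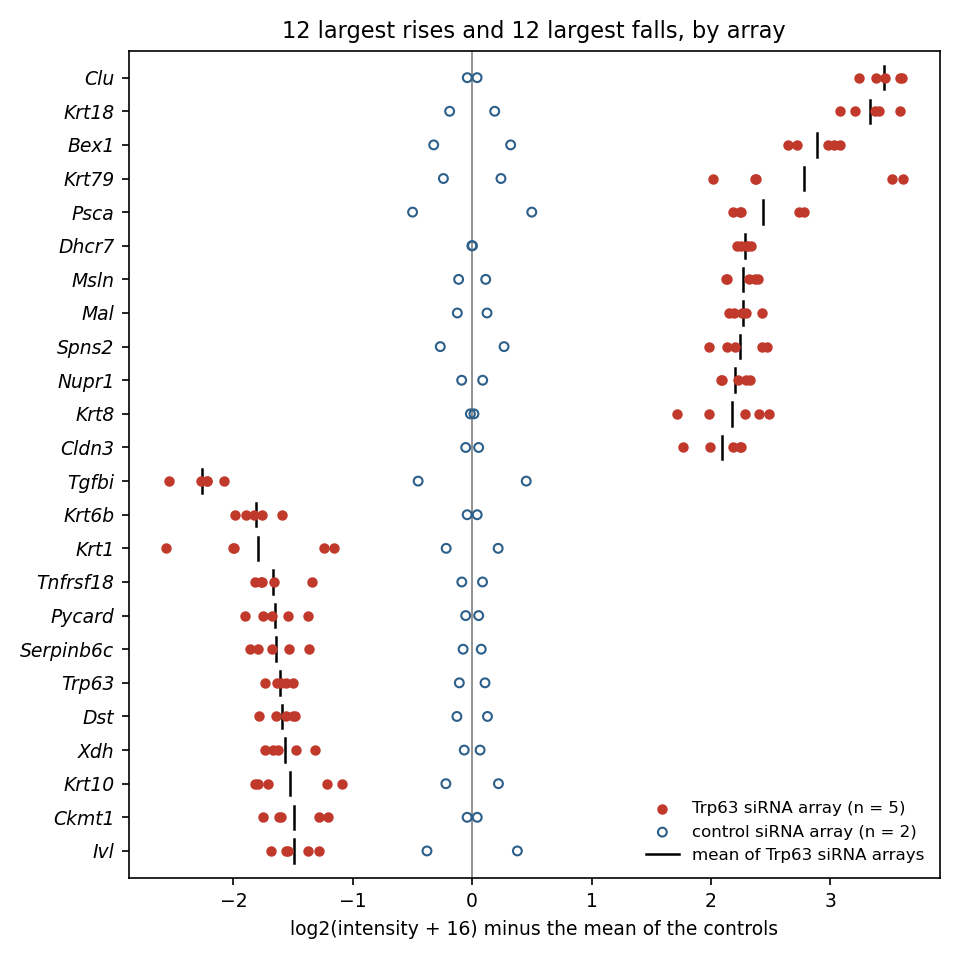
Log2(intensity + 16) of each array minus the mean of the 2 controls (x axis) for the 12 largest rises and 12 largest falls (y axis), with filled points for the 5 Trp63 siRNA arrays, open points for the 2 controls and a black tick for the mean of the silenced arrays. Clu had a mean difference of 3.45 and Tgfbi one of -2.27. The rule that chose these genes required that no silenced array overlapped the controls.

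Of 24 measured genes of epidermal adhesion, which anchor basal cells to the basement membrane and to each other, 12 fell, 2 rose and 10 did not pass (15 and 2 adjusted over the list alone). Dst, the integrin genes Itgb4 (log2 difference -1.06, SE 0.13) and Itga6 (-0.89, SE 0.090), and Col17a1 (-0.96, SE 0.10) were among the falls, while Ppl, which encodes the cornified envelope protein periplakin, rose 1.85-fold. The list was lower than other genes (limma camera, adjusted p = 0.00206), with adjusted p = 0.425 with an estimated correlation. Of 20 basal keratinocyte genes, 11 fell, 3 rose and 6 did not pass (13 and 3 adjusted over the list alone). The transcription factor genes Sox15 (-0.84) and Bcl11b (-0.78) and the receptor gene Fgfr2 (-0.75) fell, the basal keratin gene Krt5 fell 1.25-fold, and Wnt7b rose 2.01-fold. This list was also lower by camera (adjusted p = 0.00255), with adjusted p = 0.504 with an estimated correlation.

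Differentiation genes moved in both directions. Of 35 measured members, 12 rose, 6 fell and 17 did not pass (17 and 7 adjusted over the list alone). The count that rose was 3 without control replicate 6, 17 without control replicate 5, 7 without silenced replicate 2 or 7, 6 with the spike split as a block and 18 with the melanocyte split as a block. Krt1, Krt10, Ivl, Hrnr (log2 difference -1.02, SE 0.16) and Krtdap (-0.58, SE 0.078) fell. Flg (0.99, SE 0.11), Lor (0.87, SE 0.20), Lce1b (1.94, SE 0.31), Lce1a1 (1.81, SE 0.35) and the keratin gene Krt77 (1.56, SE 0.18) rose. The list median was 0.21, and camera called it higher (adjusted p = 0.00644), with adjusted p = 0.644 with an estimated correlation. Krt1 lost its call without control replicate 5 (limma adjusted p = 0.0861), and Lor, Lce1a1 and Lce1b lost theirs without control replicate 6 (limma adjusted p = 0.185, 0.106 and 0.0557). Members of the keratin and Lce families resemble each other in sequence, and their probe sets may share signal.

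Among 21 genes of activated keratinocytes, 6 rose, 3 fell and 12 did not pass (9 and 6 adjusted over the list alone). The cytokine genes Il1a (log2 difference 1.80, SE 0.21) and Ccl20 (1.57, SE 0.21), the urokinase receptor gene Plaur (0.77, SE 0.066) and Mmp13 (0.45, SE 0.051) rose, whereas the keratins of wounded epidermis, Krt6b (-1.81), Krt16 (-0.62) and Krt6a (-0.26), fell. Mmp13 was dim in both groups (110 with Trp63 siRNA against 76.3 in controls). Camera called the list higher (adjusted p = 0.0211), with adjusted p = 0.504 with an estimated correlation. The near-identical sequences of Krt6a and Krt6b leave the split between them uncertain, and Krt16 lost its call when either control was left out (limma adjusted p = 0.151 without replicate 5 and 0.0888 without replicate 6).

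Of 28 measured genes of mitosis, 10 fell, none rose and 18 did not pass (24 and 0 adjusted over the list alone), and the list median was -0.42. The count that fell was 0 without control replicate 6, 22 without silenced replicate 1, 1 with the spike split as a block and 27 with the melanocyte split as a block. Mitotic genes averaged -0.60 and -0.61 against the controls in silenced replicates 1 and 2, the silenced arrays of high melanocyte level, and -0.38, -0.30 and -0.29 in replicates 3, 4 and 7. The list median was -0.41 within the arrays of high melanocyte level and -0.45 within those of low level. Tpx2 (log2 difference -0.44, SE 0.081), Cenpa (-0.49, SE 0.11), Kif23 (-0.47, SE 0.11) and Cdc20 (-0.43, SE 0.094) fell, and each lost its call without control replicate 6 (limma adjusted p between 0.0838 and 0.155). Camera called the list lower (adjusted p = 3.8e-06), with adjusted p = 0.504 with an estimated correlation. Of 27 DNA replication genes, 4 fell (Pola1, Prim1, Gins1 and Mcm10), none rose and 23 did not pass (4 and 0 adjusted over the list alone), with no call (adjusted p = 0.144). Prim1, Gins1 and Mcm10 lost their calls when either control was left out, so 1 gene fell in each case. The replication list averaged -0.22 and -0.32 in silenced replicates 1 and 2 and -0.07, -0.01 and -0.02 in replicates 3, 4 and 7. Of 28 genes of the p53 pathway, 8 fell, 3 rose and 17 did not pass (8 and 4 adjusted over the list alone), and 3 fell without control replicate 6 and 5 without control replicate 5. Dcxr (-1.10), Fas (-0.69) and Sfn (-0.60) fell and Plk2 (0.47) rose, and the list was not called by camera (adjusted p = 0.128).

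Of 22 genes of the mesenchymal programme, 10 rose, 2 fell and 10 did not pass (10 and 3 adjusted over the list alone). Ccn2, encoding a matrix-associated growth factor partner, rose 3.16-fold, S100a4 rose 2.64-fold and the fibronectin gene Fn1 rose 2.19-fold. Snai2, a transcription factor gene of the same programme, fell 2.33-fold (log2 difference -1.22, SE 0.067, limma adjusted p = 1.1e-05). Camera called the list higher (adjusted p = 4.0e-05), with adjusted p = 0.285 with an estimated correlation. Fibroblast markers moved the same way by camera (adjusted p = 0.0211, and adjusted p = 0.504 with an estimated correlation), with Col5a2 1.73-fold and Col1a1 1.36-fold higher. Of 19 genes of EGFR ligands and MAPK feedback, 7 rose, 2 fell and 10 did not pass (7 and 3 adjusted over the list alone). Errfi1 (1.24, SE 0.065), a feedback inhibitor of the EGF receptor, Dusp1 (0.99, SE 0.14), Ets1 (0.69, SE 0.067) and Phlda1 (0.55, SE 0.077) rose. This list was called higher (adjusted p = 0.00187), with adjusted p = 0.285 with an estimated correlation.

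Other signalling lists held strong single changes without a call for the list. Of 20 Notch pathway genes, 3 rose, 3 fell and 14 did not pass, the same counts as adjusted over the list alone. The receptor gene Notch1 fell 2.47-fold (log2 difference -1.31, SE 0.12) and the ligand genes Dll1 and Jag2 fell 2.05-fold and 1.36-fold, while Rbpj, the DNA-binding partner of the pathway, rose 1.37-fold (camera adjusted p = 0.998). Jag2 lost its call without control replicate 6 (limma adjusted p = 0.0962) and with the spike split as a block (0.0512). No Notch gene rose without control replicate 5, and 1 rose and 2 fell without control replicate 6. Of 29 TGF-beta and BMP genes, 7 rose, 5 fell and 17 did not pass (8 and 7 adjusted over the list alone), and 2 fell without control replicate 6. Thbs1 rose 2.76-fold, Tgfb3 1.92-fold and the inhibitor gene Smad7 1.53-fold, opposite to Tgfbi (camera adjusted p = 0.144). Control values of Tgfb3 were dim (96.0, against 200 with Trp63 siRNA). Of 25 Wnt genes, 1 rose (Fzd7, 0.55), 1 fell (Fzd6, -0.94) and 23 did not pass, the same counts as adjusted over the list alone. Fzd7 lost its call without control replicate 6 (limma adjusted p = 0.0504) and without control replicate 5, so 0 rose in both cases. The Wnt median and mean were slightly below 0 (-0.03 and -0.04) although camera's uncalled direction was up (adjusted p = 0.998). Of 16 AP-1 and immediate early genes, 2 rose (Jund, 0.31, and Ier3, 0.17), none fell and 14 did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.153). Jund lost its call without control replicate 5 (limma adjusted p = 0.169) and Ier3 without either control or any of silenced replicates 3, 4 and 7, so 0 rose and 1 fell without control replicate 5. Of 26 hair follicle and appendage genes, 2 rose (Krt79 and Sox9, 0.35), 2 fell (Ptch1, -0.76, and Hoxc13, -0.60) and 22 did not pass, the same counts as adjusted over the list alone. Sox9 lost its call without control replicate 6 (limma adjusted p = 0.177) or silenced replicate 7 (0.0517). The median of this list was -0.03, its mean 0.06, and camera made no call (adjusted p = 0.872).

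Of 18 measured genes of cholesterol synthesis, 7 rose, none fell and 11 did not pass (8 and 0 adjusted over the list alone), and 2 rose without control replicate 6, 1 within the arrays of low spike level and 10 with the melanocyte split as a block. Beside Dhcr7, the other named members rose by less: Ebp 1.40-fold, Msmo1 1.33-fold and Nsdhl 1.32-fold, the last pair losing their calls without control replicate 6 (limma adjusted p = 0.0957 and 0.0504). Camera called the list higher (adjusted p = 3.7e-05), with adjusted p = 0.425 with an estimated correlation. Of 20 genes of endoplasmic reticulum and amino acid stress, 7 rose, 1 fell and 12 did not pass (8 and 2 adjusted over the list alone), and 1 rose without control replicate 5, 2 without control replicate 6 and 2 with the spike split as a block. The chaperone gene Hspa5 rose 1.41-fold, Creld2 1.54-fold and Sel1l 1.32-fold, and Shmt2, of serine metabolism, fell 1.38-fold. Hspa5 and Shmt2 lost their calls without control replicate 6, Sel1l without control replicate 5 and Creld2 without either. The list was called higher (adjusted p = 0.00644), with adjusted p = 0.504 with an estimated correlation. Of 25 interferon response genes, 3 rose (Bst2, 1.99-fold, Rtp4, 1.39-fold, and Oasl2, 1.27-fold), none fell and 22 did not pass, the same counts as adjusted over the list alone. Rtp4 and Oasl2 lost their calls when either control was left out, and Oasl2 was dim in both groups (109 with Trp63 siRNA against 82.3 in controls). Camera called the interferon list higher (adjusted p = 0.00781), with adjusted p = 0.504 with an estimated correlation, although its median was 0.05.

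A list of direct p63 targets taken from general knowledge of the literature had 20 measured members, of which 7 fell, 2 rose and 11 did not pass, the same counts as adjusted over the list alone. Dst, Fgfr2, Sfn and Krt14 were among the falls (the Krt14 probe set was the brightest on both control arrays, so its 1.15-fold difference may be compressed), 2 genes rose with all arrays but none without control replicate 6, and camera made no call (adjusted p = 0.131).

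**Figure D3:**
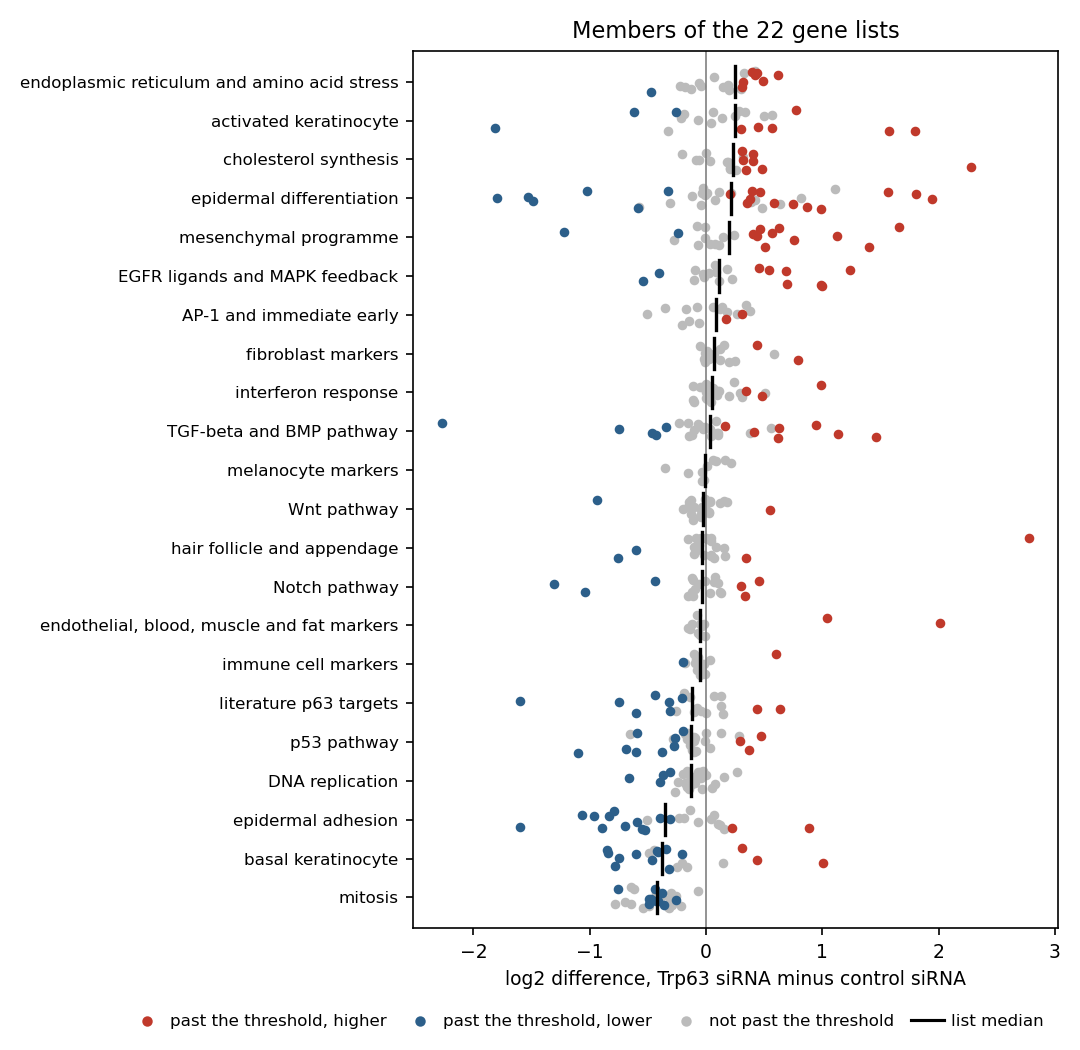
Log2 difference (Trp63 siRNA minus control siRNA, x axis) of each measured member of the 22 gene lists (y axis), ordered by list median (black tick). Coloured points passed limma's test at an adjusted p of 0.05. The median was lowest for mitosis (-0.42) and highest for endoplasmic reticulum and amino acid stress (0.25).

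Markers of other cell types were low or did not separate the groups, with few exceptions. Of 17 fibroblast genes, 2 rose (Col5a2, 1.73-fold, and Col1a1, 1.36-fold), none fell and 15 did not pass. Col1a1 lost its call without control replicate 6 (limma adjusted p = 0.0504), and the brightest other named member, Col6a2, read 282 against 259. Camera called this list higher (adjusted p = 0.0211), with adjusted p = 0.504 with an estimated correlation. Of 10 melanocyte genes none passed, with medians near 0 (-0.004, camera adjusted p = 0.816). Dct read 3136 ± 1048 (SD, n = 5) against 3101 ± 916 (SD, n = 2), and Pmel 2127 ± 706 against 1872 ± 631. Tyr and Slc45a2, the members with the smallest p, differed by -0.35 and -0.15 (limma adjusted p = 0.247 and 0.542). With the melanocyte split as a block Tyr (-0.30, limma adjusted p = 0.00682) and Pmel (0.24, limma adjusted p = 0.0071) passed in opposite directions. That split was defined by the mean level of this same list. The block thus removes spread of these genes by construction, and their calls under it decide nothing. Of 16 immune cell genes, 1 rose (Cd68, 1.51-fold), 1 fell (Tyrobp, 1.15-fold) and 14 did not pass. Tyrobp lost its call without either control (limma adjusted p = 0.0971 and 0.112) and Cd68 without control replicate 6 (0.226) or silenced replicate 2 or 7, so none passed without control replicate 6. The 2 brightest, Csf1r and Cd3e, differed by -0.06 and -0.18 (camera adjusted p = 0.461). Of 12 endothelial, blood, muscle and fat genes, 2 rose (Fabp4, 4.03-fold, and Acta1, 2.06-fold), none fell and 10 did not pass, with a median of -0.05, a mean of 0.19 and no camera call (adjusted p = 0.994). For the fibroblast, melanocyte, immune and mixed marker lists, counts adjusted over the list alone were the same.

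Over the whole array, 3618 of 22626 probe sets passed limma's test at an adjusted p of 0.05, 1771 higher and 1847 lower with Trp63 siRNA. By gene, 995 were higher and 1061 lower among 12393, and 183 of these 2056 changed by at least 2-fold (136 higher, 47 lower). The 5 silenced values lay on 1 side of both controls in 38.3% of genes, where chance gives 9.52%. The first principal component held 59.3% of the variance and separated the groups, with silenced arrays between -14.8 and -9.89 and controls at 25.7 and 32.1. The second held 27.0% and set silenced replicate 1 (25.5) apart from the other silenced arrays (-12.6 to 3.54), with controls at 6.78 and -3.13. Of the 118 named genes past the threshold 47 had several probe sets, of which none had a probe set past it the other way and 18 had at least 1 that did not pass.

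The groups also differed in RNA quality, measured as the log2 ratio of 3′ to 5′ control probe sets. For beta-actin the ratio was 0.24 ± 0.052 (SD, n = 5) with Trp63 siRNA and 0.41 ± 0.040 (SD, n = 2) in controls, and for Gapdh -0.12 ± 0.020 and -0.03 ± 0.0029. Both had an exact two-sided permutation p of 0.0476, the smallest that the 21 splits allow. This difference moved with the groups and so with every gene list above.

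Arrays of the same group also differed from each other. Probe sets for bacterial spike transcripts averaged 8.70 to 8.87 (log2) in silenced replicates 2, 3 and 7 and 8.20 to 8.39 in silenced replicates 1 and 4 and both controls. The melanocyte genes averaged 9.19 to 9.29 in silenced replicates 1 and 2 and control replicate 5, and 8.77 to 8.82 in the other 4 arrays. The sign of the second principal component followed the same split. It was positive in those first arrays (25.5, 3.54 and 6.78) and negative in the other 4 (-12.6 to -3.13). Krt79, a gene outside the list, was also higher in silenced replicates 1 and 2 (2004 and 1884) than in 3, 4 and 7 (656 to 845). Other genes were not tested for this split. With the melanocyte split as a block 3135 genes passed. The arrays of high and of low melanocyte level held 1 control each. Counts within them lean on that lone control, so they appear only in the part on processing and carry no conclusion. With the spike split as a block 1117 genes passed, and 472 did within the arrays of low spike level, where alone both groups occur. For a given probe set these fits share 1 log2 difference, that of silenced replicates 1 and 4 against both controls. They differ only in how spread is estimated, so they are not separate evidence. Trp63 fell in each of these fits and within both melanocyte levels. All 11 lists called by camera had medians of the same sign within the high-melanocyte, low-melanocyte and low-spike arrays. These subsets are parts of the arrays that gave the calls, so the same sign is weak evidence. The median nearest 0 was 0.009, for interferon response within the high-melanocyte arrays.

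**Figure D4:**
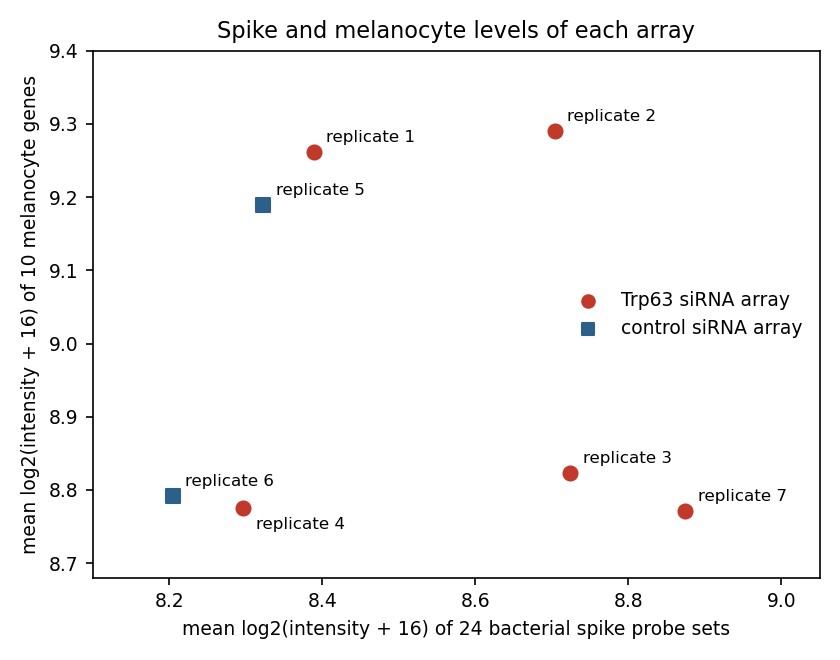
Mean log2(intensity + 16) of the 24 bacterial spike probe sets (x axis) and of the 10 melanocyte genes (y axis) in each array, with circles for Trp63 siRNA and squares for control siRNA. Silenced replicates 2, 3 and 7 had the highest spike level, and silenced replicates 1 and 2 shared the high melanocyte level of control replicate 5.

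The number of genes past the threshold depended on single arrays, at 804 without control replicate 6, 1190 without control replicate 5 and 3175 without silenced replicate 1, against 2056 with all arrays. Without control replicate 6 the camera calls for epidermal differentiation (adjusted p = 0.213), activated keratinocyte (0.235), interferon response (0.122) and fibroblast markers (0.464) ended, and without control replicate 5 that for endoplasmic reticulum and amino acid stress ended (0.0747).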

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

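Among the tests reported here, the one of the share of melanocytes was chosen after the result was seen. Of 149 named genes and gene list levels, 13 had 1 of the 5 silenced arrays set apart from the rest by more than Dixon's 95% criterion, where chance gives about 7.45. Replicate 1 was the array set apart in 6 of them, replicate 3 in 4 and replicate 2 in 3. In silenced replicate 1 Smad7 was highest (gap to the nearest array 0.909 of the range), as were Dll1 (0.837), Elf5 (0.816) and Trp73 (0.758), and Pola1 was lowest (0.811). The mesenchymal programme was also highest there (0.809). A high ratio can come from a small gap where the arrays lie close together. Smad7 was 8.41 (log2) in silenced replicate 1 and 8.36 in the other silenced arrays, and the mesenchymal list 9.24 against 9.15 to 9.17. Silenced replicate 2 had the lowest Cenpa (0.892), the highest Hspa5 (0.715) and the highest level of the endoplasmic reticulum and amino acid stress list (0.716). Silenced replicate 3 had the lowest Snai2 (0.754), the highest Ier3 (0.715), the lowest Lor (0.716) and the lowest level of the epidermal differentiation list (0.812).

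Bacterial spike transcripts, which belong to no comparison of genes, were 0.50 (log2) above the mean of the 2 controls in silenced replicates 2, 3 and 7. No explanation of this difference was tested, and it concerns silenced arrays alone.

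The melanocyte genes differed between arrays of the same group, with silenced replicates 1 and 2 and control replicate 5 above the other 4 arrays. Dct, Pmel and Tyrp1, the 3 brightest of 10, were higher by 0.84, 0.84 and 0.68 on the log2 scale in silenced replicates 1 and 2 than in replicates 3, 4 and 7, while Kit (0.38), Mitf (0.31), Sox10 (0.16) and Ednrb (0.07) shifted less. The smallest shift of the brightest 3 was 0.806 of their median, but the split was defined by the level of these same genes, so this value does not test an unequal share of melanocytes, which stays open. A labelling batch marked by the spike transcripts is argued against, since silenced arrays of high and low spike level differed in mean melanocyte level by only -0.057, below the range within each set (0.49 or more). The design names no biological difference between these arrays, so no biological explanation was tested, and the cause of the unequal levels stays open.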

How the results depend on the processing

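The spike and melanocyte splits, as a block or within arrays, were chosen after seeing the data, and the other alternatives before the data were examined. Trp63 knockdown kept its direction and its call under every alternative run for it, between -1.71 and -1.50 when 1 array was left out and at -0.88 with the mean of its probe sets. Of 118 genes named and called, none lost its call with median centring or with either other pseudocount, 1 did with quantile normalisation (Ier3), 18 did without control replicate 5, 28 without control replicate 6, 17 with the spike split as a block and 40 within the arrays of low spike level. A lone control is assumed to vary like the silenced group, and fewer arrays are part of why calls end. Slc2a3 turned to -0.10 (limma adjusted p = 0.225) when a probe set not marked as shared was used, and the cause was not tested. Counts of at least 2-fold changes stayed within 1.5 times under leaving out 1 array. Leaving out 1 array moved probe sets past the threshold between 1374 and 5502 (higher 776 to 2326, lower 598 to 3176) and genes between 804 and 3175 (higher 465 to 1280, lower 339 to 1895), each time lowest without control replicate 6 and highest without silenced replicate 1. Genes lower without silenced replicate 7 were 705. Array weights gave 2823 lower probe sets and 1672 lower genes. With the spike split as a block there were 1920 probe sets (1135 higher, 785 lower) and 1117 genes (441 lower), and within the arrays of low spike level 783 (537, 246) and 472 (321, 151). With the melanocyte split as a block there were 5458 probe sets (2895 lower) and 3135 genes (1687 lower), all 2056 genes of the full fit kept among them. Within the arrays of high melanocyte level there were 1870 (874, 996) and 1040 (509, 531), and within those of low level 6883 (3199, 3684) and 3977 (1748, 2229).

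All 11 camera calls ended with an estimated correlation, with adjusted p of 0.285 for the mesenchymal and EGFR lists, 0.425 for adhesion and cholesterol, 0.504 for basal, activated, mitosis, interferon, stress and fibroblast, and 0.644 for differentiation. With the melanocyte split as a block as well, they were 0.369 for mesenchymal, EGFR and mitosis, 0.379 for adhesion and cholesterol, 0.448 for fibroblast, 0.522 for basal, 0.575 for activated, and 0.597 for differentiation, interferon and stress. Leaving out 1 array moved camera's adjusted p between 3.3e-05 and 0.213 for differentiation, 0.00194 and 0.235 for activated, 0.0278 and 0.472 for p53, 0.0178 and 0.739 for DNA replication, 0.00216 and 0.122 for interferon, 0.0482 and 0.532 for TGF-beta, 0.00181 and 0.0747 for stress, 0.0221 and 0.397 for literature targets, and 0.00139 and 0.464 for fibroblast. The p53 list passed without silenced replicate 3 (0.0444), silenced replicate 7 (0.0455) or control replicate 5. The activated list ended at the 25th percentile filter (0.130) and at the 50th (0.440), with the spike block (0.0558) and with the melanocyte block (0.0513). At the 50th percentile filter interferon (0.2498) and stress (0.0541) ended and the endothelial, blood, muscle and fat list passed (0.0126), with fewer genes tested. The spike block gave 0.0880 for stress and 0.0420 for p53, and the low-spike arrays 0.0216 for p53. The causes of these list changes were not tested. The lowest intensities, near 60 on each array, set a floor under which changes of dim genes cannot be read.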

Other observations

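Of the tests reported in this part, the simple epithelium, Merkel, mesothelial and sebaceous lists and the 14 gene families were chosen after the largest changes were seen, while the count of splits was planned before the data were examined and its bound was worded after. More members of the list written for simple epithelia rose than those named so far. Of 23 measured genes of that list, 16 rose and none fell (16 and 1 adjusted over the list alone), with a median log2 difference of 1.16, and since 6 of the 23 were already known as largest rises the list is not independent evidence of its direction. Of the other 17, 10 rose and none fell. Epcam, a surface adhesion gene, rose 3.39-fold (log2 difference 1.76, SE 0.12), and Prom1 rose 3.34-fold. The claudin genes Cldn7 and Cldn4 rose 2.48-fold and 2.40-fold, Elf5 2.23-fold and Krt7 2.08-fold. Controls of Cldn7, Elf5, Prom1 and Krt7 read only 115, 123, 160 and 174, so the folds of these genes may be understated. Other members that rose were already well above the array medians in controls, such as Cldn4 (2090), Epcam (825), Spint1 (811) and Mal (603). The name of the list therefore does not by itself give a cell type or programme. Krt19 (0.11), Muc1 (-0.05), Cdh16 (0.009), Cldn6 (-0.18), Ehf (-0.08), Tspan1 (-0.02) and Tspan8 (-0.06) did not pass. Camera, adjusted over the lists written after the largest changes were known, called the 23 genes together higher. It gave adjusted p = 2.5e-15 with the preset correlation and adjusted p = 0.0246 with the estimated one. These values include the 6 known rises, and the other 17 genes were not tested alone.

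Of 4 tissue inhibitors of metalloproteinases, 3 rose and none fell, namely Timp2 (log2 difference 1.87, SE 0.14), Timp3 (1.82, SE 0.10) and Timp1 (0.73, SE 0.076). Of 15 kallikreins, the serine proteases of the shedding epidermis, 5 rose, none fell and 10 did not pass, with a family median near 0, and Klk6 stood at 1.90 (SE 0.33), Klk7 at 1.52, Klk8 at 1.04, Klk10 at 0.91 and Klk11 at 0.58, the last without a call when control replicate 5 was left out (limma adjusted p = 0.0741). Camera adjusted over the 14 families gave p = 0.00016 and 0.0227 for these families, and adjusted p = 0.108 and 0.535 with an estimated correlation. Of 11 S100 proteins 5 rose and none fell (adjusted p = 0.00016, and adjusted p = 0.179 with an estimated correlation). The glucose transporter gene Slc2a1 fell 1.98-fold while Slc2a3 rose 2.83-fold at its brightest probe set. That rise is uncertain, since of the 4 Slc2a3 probe sets the 2 that rose are marked as shared with other transcripts and the others, at 0.11 and -0.10, did not pass. The cytokine gene Il18 fell 2.17-fold and the receptor gene Il18r1 rose, a call that ended without control replicate 5 (limma adjusted p = 0.0732) and with the spike split as a block (0.0515). Of the 14 families looked at, 4 were called by camera, the other being the vacuolar ATPase subunits (4 rose and 2 fell of 19, adjusted p = 0.00676), and none kept its call with an estimated correlation (adjusted p = 0.633 for the last). The counts that rose and fell in these named families were the same with quantile normalisation and median centring.

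For the rise of simple epithelium genes, uneven RNA quality stays open. Within the 5 silenced arrays the mean level of the 16 called members was set against the beta-actin ratio. Its slope was 0.024 of the slope that the group difference needs, with an upper 95% bound of 0.13. This does not decide the question, since those members were picked by a fit that favours a small spread within groups. Admixed Merkel or mesothelial cells stay open. Of 14 Merkel genes 1 rose and none fell. Of 11 mesothelial genes 2 rose (Efemp1, 1.89-fold, and Cpe, 1.40-fold) and 2 fell, and the higher list median was -0.044. In controls 0 of the Merkel and 4 of the mesothelial genes reached the median level of all probe sets. Merkel genes such as Krt20 (97.6 with Trp63 siRNA against 105 in controls) and Chga (131 against 134) were dim in both groups. Whether such probe sets would read these cells is not shown, so the lists do not exclude them, although this had been set as the test. Msln, also a mesothelial gene, had been placed in the simple epithelium list. The melanocyte split as a block left 16 of 16 called members past the threshold, which decides nothing, since the split is nearly balanced over the groups and the block ended 0 of 2056 calls. A change of the silenced keratinocytes themselves and an effect of the siRNA on other targets stay open as well.

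Movement of differentiation genes in both directions was kept by all 18 called members with the melanocyte split as a block, which for the same reason decides nothing. Signal shared between near-identical genes cannot be told apart from real changes here. Preferring probe sets not marked as shared kept all 18 calls, but it exchanged no probe set of these genes and so decides nothing. What sets the genes that rose apart from those that fell was not tested.

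The rises of Krt79, Psca and Fabp4 raised the hypothesis of a sebaceous programme. Of 12 sebaceous genes 5 rose, among them Dgat2 (1.54-fold), Scd1 (1.47-fold) and Plin2 (1.29-fold), and none fell. The median was 0.16, below the bound of 0.25 set for rejecting the hypothesis, although camera called the list higher (adjusted p = 0.00585, and adjusted p = 0.522 with an estimated correlation). Scd1 and Dgat2 lost their calls without control replicate 6 (limma adjusted p = 0.0595 and 0.115), while Cidea, which did not pass (2.14-fold, limma adjusted p = 0.0631), did so with the melanocyte split as a block (5.5e-05).

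Of the 21 splits of the 7 arrays into 5 and 2, 1 gave as many probe sets past the threshold, the real one with 3618. The highest count of any other split was 0. That rank gives an exact permutation p of 0.0476, the smallest that 21 splits allow. Chance assignment of the arrays is argued against only at that level. It is not excluded, since the labels do not say whether replicates were separate cultures.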
